A study of Mus musculus with 6 samples.

How the data were processed

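Gene expression was measured in cultured mouse embryonic fibroblasts, the connective-tissue cells that grow out of dissociated embryos, on 6 Agilent long-oligonucleotide arrays hybridised with 2 labelled samples each. Per the labels, the embryos were 15.5 days old, the mice had a mixed background that includes Black Swiss, and cytoplasmic RNA was taken at passage 2, which the design text puts at 10 population doublings. Per the design text, each RNA pool came from 3 embryos of 1 litter, and another litter gave a second pool of every genotype. There were 3 mutant genotypes with 2 arrays each. The Wrn mutant carries an in-frame deletion in the helicase part of Wrn, the RecQ helicase and exonuclease lost in human Werner syndrome. The PARP-1 null cells lack poly(ADP-ribose) polymerase 1, an enzyme that senses DNA strand breaks, and the double mutant has both changes. Groups were taken from the titles and source labels. For the duplicate double-mutant array these name the double mutant, while the strain label of the same channel reads wild type, and this array was also left out as an alternative.

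Per the labels, wild-type cRNA carried Cy5 and mutant cRNA Cy3 on every array, so dyes were never swapped. The wild type was the partner on each array and had no array of its own. A test of a ratio against 0 therefore holds any dye bias of a probe. It may also leave out part or all of the wild type's own spread, depending on the wild-type pools used. A dye bias cancels in the difference between 2 mutants. Which wild-type pool was on which array, and whether the duplicate array held the pool of the second litter, is not given in the sources used here. The p-values thus measure the spread between these arrays, which may be partly technical.

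The authors deposited 1 log ratio per spot, taken here as log10, for 22393 spots on each array. The base was read from the values, which stop exactly at a size of 2 on every array, and is itself not stated. The median was 0 on all 6 arrays. The centring and background methods, the spot filters and the direction of the ratio are not given in the sources used here. No value was missing, and between 16.9% and 23.7% of the spots of an array were exactly 0. Whether an exact 0 is a measured ratio or a placeholder is not stated. Signal intensities were not used here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision. Values were multiplied by log2 of 10, which is 3.32, to put them on the log2 scale. Positive values were read as mutant over wild type. This direction is likely, not certain: Parp1 lay far below 0 on the 4 arrays of cells without PARP-1 only, while Agilent's usual Cy5 over Cy3 with the stated dyes would give wild type over mutant. Turning the sign would mirror every direction reported.

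Spots were named through the platform annotation, which gave 1 symbol for 18218 spots, several for 16 and none for 4159. Spots of one gene were averaged, which gave 16504 named genes, and the 4175 other spots were kept as single features, for 20679 features in all. Of the named genes, 1193 had more than 1 spot, with a median range between spots of 0.59 on the log2 scale, and for 272 of them the range was above 1. RefSeq genes of the mouse assembly GRCm38.p6 held 16462 of the named genes by Entrez ID and served only to find gene neighbours, since the build behind the array was not given.

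Features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with the data.table package 1.17.8) in 1 fit of all 6 arrays with a coefficient per genotype. The fit had 3 residual degrees of freedom, to which the empirical Bayes prior added 0.66. P-values were adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05, and counts given here are of named genes. Each genotype was compared with wild type, the genotypes with one another, the double mutant with the sum of the single mutants, and the mean of all mutants with wild type. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

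Gene lists, 42 in number and chosen for DNA repair, p53, apoptosis, cell cycle, stress, matrix, metabolism and cell types an embryo culture can hold, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 42 lists of a comparison. Of their 1505 members, 1378 were measured. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move one way on balance, were run as alternatives. The count of members that passed is given over all features and adjusted over the list alone. Named genes were, for each comparison with wild type and for the double mutant against each single mutant, the 10 largest positive and 10 largest negative values among genes that passed with the same sign on both arrays. Where fewer passed, the 10 were filled by the largest values of the smaller of the 2 arrays, or of the smallest gap between arrays of 2 mutants, and these are said not to have passed. Parp1, Wrn and up to 4 members of each list that passed were also named. Clone names were skipped, which happened once in each of 2 comparisons. Genes within 20 Mb of a targeted gene were compared with all others by Fisher's exact test, two-sided, adjusted over 6 tests. Overlaps were set against independent lists, and correlations of group means against 20 simulations of unchanged groups. Same-numbered arrays shared their wild-type values there, and wild-type and mutant values had equal spread, which fixes the simulated correlation.

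Groups, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives were array scaling and centring, features without an exact 0, robust empirical Bayes, the array number as a block, each array left out, a comparison's own arrays only, and a 2-fold rule. Single spots in place of gene means were planned too. Chosen after seeing the data were centring on the mean, named genes alone, leaving out features at exactly 0 on all arrays, lists without genes at exactly 0 on any array, the genes that set apart the arrays without PARP-1, and correlations over unnamed spots. The procedure was tested on simulated data in which 100 genes of the PARP-1 null were changed at each size. At a log2 change of 1 it called 9% of them among 20679 features, at a change of 2 it called 36%, and it called 4 unchanged features. Among the 14444 features without an exact 0 the shares were 10% and 64%, with 0 unchanged features called. A simulated shift of 0.5 in the mitosis genes gave a camera adjusted p of 2.14e-27 at the preset correlation and 0.0951 with an estimated correlation. The simulated noise was independent between genes, so it cannot tell which correlation setting suits lists of genes that vary together.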

Results

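Cultured embryonic fibroblasts of 3 mutant genotypes, a Wrn helicase deletion, a PARP-1 null and the double mutant, were each compared with wild type on 2 arrays. Parp1 fell in both lines that lack the enzyme: the log2 ratio, read as mutant over wild type, was -2.45 ± 0.22 (SD, n = 2) in the PARP-1 null and -2.78 ± 0.27 (n = 2) in the double mutant (limma, Benjamini-Hochberg adjusted p = 0.0104 in each). In the Wrn mutant it was -0.22 ± 0.13 (adjusted p = 0.420 in limma with Benjamini-Hochberg). Per array, the Parp1 values were -2.61 and -2.30 in the PARP-1 null, -2.97 and -2.59 in the double mutant, and -0.12 and -0.31 in the Wrn mutant. The array labelled as the duplicate of the double mutant, whose strain label says wild type, is the one at -2.59. The direction rests on these Parp1 values and is likely, since a turned sign would mean that cells without PARP-1 had more of its mRNA. The adjusted p of Parp1 was 0.0511 without the first and 0.0877 without the second PARP-1 null array, and 0.0714 and 0.0513 in the double mutant without its first and second array (limma, Benjamini-Hochberg). The Wrn probe did not pass in any genotype, at 0.71 ± 0.19 in the Wrn mutant, -0.12 ± 0.24 in the PARP-1 null and 0.48 ± 0.33 in the double mutant (n = 2 each). Whether this probe lies inside the deleted part is not given in the sources used here: outside it the probe checks nothing, and inside it 0.71 would go against the label, so the Wrn labels were not checked.

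In the Wrn mutant the largest increases were in Pdgfrl, a gene related to the PDGF receptor, at 3.19 ± 0.40 (mean ± SD, n = 2), and in the imprinted growth factor Igf2 at 2.64 ± 0.24. The imprinted gene Mest rose by 2.32 ± 0.22 in the Wrn mutant alone, with 0.17 ± 0.052 in the PARP-1 null and -0.68 ± 0.45 in the double mutant (n = 2). The corepressor gene Hr rose by 2.30 ± 0.51, the kidney transcription factor gene Pax2 by 2.27 ± 0.055, and Serpina6, which encodes corticosteroid-binding globulin, by 2.24 ± 0.50. Rgn rose by 2.22 ± 0.082, Tnfsf14 by 2.20 ± 0.41, Serpinb6b by 2.16 ± 0.54 and the lipopolysaccharide-binding protein gene Lbp by 2.16 ± 0.67 (n = 2). Among genes that fell were Cplx1, a complexin of synaptic vesicle release, at -3.79 ± 0.62, the X-linked Xlr5c at -3.69 ± 0.55 and Serpinb9c at -3.64 ± 0.69. Lypd3 (-3.25 ± 0.069), Cited4 (-3.23 ± 0.50) and the estrogen receptor beta gene Esr2 (-2.83 ± 0.80) fell too. So did the olfactory receptor gene Olfr355 (-2.82 ± 0.67), the mast-cell protease gene Mcpt8 (-2.82 ± 0.28), the defensin gene Defb6 (-2.57 ± 0.037) and Shroom1 (-2.48 ± 0.67) (n = 2). Their adjusted p-values ran from 0.0152 to 0.0483 (limma, Benjamini-Hochberg). Most had similar values in the other genotypes: Xlr5c was -3.71 in the PARP-1 null and -4.25 in the double mutant, Pdgfrl 3.05 and 3.59, and Igf2 2.31 and 2.22. Dye bias or the wild-type pools could give such shared values as well. In all, 388 of 16504 named genes passed, 167 higher and 221 lower, and 204 of them changed at least 2-fold. The split by direction was not stable, since more genes rose than fell without either Wrn mutant array. Under scale normalization between arrays 940 passed, 450 higher and 490 lower, and with the array number as a block 0 passed. The count was 768 and 315 without the first and second Wrn mutant array and 0 without any other array, each of which feeds the shared estimate of spread. None of the 20 genes above passed with each array left out in turn, and fitted on the Wrn mutant arrays alone the count was 0.

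Interferon-response genes were shifted up in the Wrn mutant, with a list median of 0.72 over 54 genes (camera adjusted p = 0.000134; adjusted p = 0.931 with an estimated correlation). Gbp2, a guanylate-binding protein gene, rose by 1.61 ± 0.062 and Tgtp1, a T-cell GTPase gene, by 0.98 ± 0.21 (n = 2); 52 members did not pass, among them Ifi47 at 1.27 ± 0.45 and Psmb10 at -1.40 ± 0.29, which lay below 0. Adjusted over the list alone, 3 members were higher and 1 lower. The imprinted list had a median of 0.54 over 31 genes (camera adjusted p = 0.00479; adjusted p = 0.931 with an estimated correlation). Igf2 and Mest rose and 29 members did not pass, among them Peg3 at 1.20 ± 0.23 and H19 at 1.93 ± 0.24. Of the 31, 6 were higher and 1 lower when adjusted over the list alone. The macrophage and leukocyte list had a median of 0.55 over 31 genes (camera adjusted p = 0.00937; adjusted p = 0.931 with an estimated correlation) without a member that passed, over all genes or adjusted over the list alone. Mrc1 was 1.37 ± 0.13, Adgre1 1.17 ± 0.60, Cd48 1.19 ± 0.69 and Mcpt4 -1.02 ± 0.38, on the other side of 0. DNA replication genes were shifted down, with a median of -0.32 over 41 genes, 40 of them below 0 (camera adjusted p = 2.62e-05; adjusted p = 0.931 with an estimated correlation). The polymerase alpha subunit gene Pola2 fell, at -0.81 ± 0.15, and 40 members did not pass, with Ccne2 at -1.32 ± 0.12, Rpa2 at -0.70 ± 0.26 and Rfc3 at -0.92 ± 0.27. Adjusted over the list alone, 0 were higher and 3 lower. Mitosis genes had a median of -0.20 over 41 genes (camera adjusted p = 0.00479; adjusted p = 0.931 with an estimated correlation) and none passed, over all genes or adjusted over the list alone. Cenpe was -0.58 ± 0.14, Foxm1 -1.64 ± 0.44, Ndc80 -0.61 ± 0.062 and Kif2c -0.95 ± 0.15. Of all named genes 2.35% passed in the Wrn mutant, a yardstick for the members past in these lists. The 2 Wrn mutant arrays differed, with interferon medians of 0.20 and 1.11 and macrophage medians of 1.03 and 0.014. Without the first array the replication (-0.070, adjusted p = 0.161), mitosis (-0.19, 0.272) and macrophage (0.014, 0.985) lists did not pass camera.

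**Figure D1:**
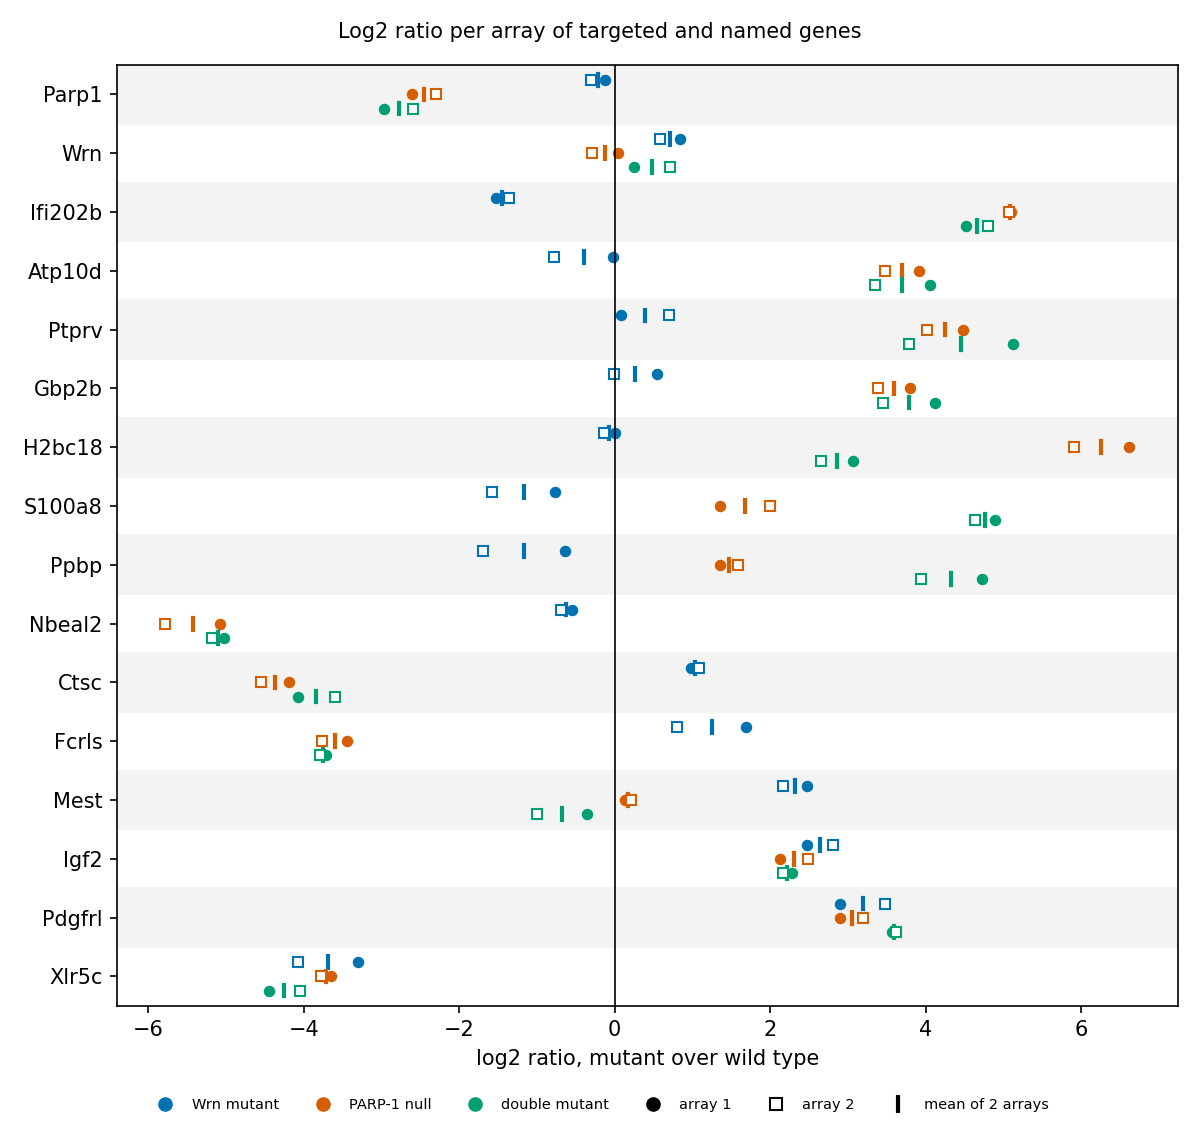
Log2 ratios of mutant over wild type for 16 genes on each array, with circles for the first and squares for the second array of a genotype and bars for the mean of 2 arrays. Parp1 lay between -2.97 and -2.30 on the 4 arrays of cells without PARP-1.

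In the PARP-1 null the histone H2B gene H2bc18 rose most, by 6.26 ± 0.51 (mean ± SD, n = 2), with -0.068 ± 0.10 in the Wrn mutant and 2.86 ± 0.29 in the double mutant. The interferon-inducible gene Ifi202b rose by 5.09 ± 0.016 and the receptor-type phosphatase gene Ptprv by 4.25 ± 0.32 (n = 2). The retinaldehyde dehydrogenase gene Aldh1a1 rose by 4.10 ± 0.26, against 2.41 ± 0.77 in the Wrn mutant. The cornified envelope genes Lce1e and Lce1i rose by 4.0 ± 0.88 and 3.96 ± 0.73, and as close paralogues they may share signal. The phospholipid flippase gene Atp10d rose by 3.70 ± 0.31, Tmem87a by 3.62 ± 0.088, the guanylate-binding protein gene Gbp2b by 3.59 ± 0.29 and Cd200, a membrane glycoprotein gene, by 3.58 ± 0.11 (n = 2). Nbeal2, needed for platelet alpha-granules, fell most, at -5.43 ± 0.50, followed by Zfp874a at -4.43 ± 0.13 and the cathepsin C gene Ctsc at -4.37 ± 0.26. In the Wrn mutant these 3 were -0.62 ± 0.093, -0.44 ± 0.19 and 1.03 ± 0.071 (n = 2). The Fc receptor-like gene Fcrls fell (-3.60 ± 0.23, against 1.25 ± 0.63 in the Wrn mutant), as did Samt2b (-3.45 ± 0.16). Serpinb9c (-3.79 ± 0.60), Xlr5c (-3.71 ± 0.095), the Notch effector gene Hes5 (-3.70 ± 0.52), the natriuretic peptide gene Nppb (-3.68 ± 0.59) and Lypd3 (-3.67 ± 0.57) fell in the PARP-1 null as well (n = 2). Adjusted p-values of these genes ran from 0.0104 to 0.0496 (limma, Benjamini-Hochberg). In all, 1187 named genes passed, 549 higher and 638 lower, 632 of them at least 2-fold. Scale normalization between arrays gave 1223, 608 higher and 615 lower, and the array number as a block gave 0. The split by direction was not stable, since more genes rose than fell without the first PARP-1 null array. The count was 594 and 56 without the first and second PARP-1 null array, 597 without either Wrn mutant array, 318 without either double-mutant array, and 0 when fitted on the PARP-1 null arrays alone. With each array left out in turn, 3 of the 20 genes passed every time, among them Ifi202b.

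Genes of oxidative phosphorylation were shifted up in the PARP-1 null, with a median of 0.43 over 56 genes (camera adjusted p = 0.000226; adjusted p = 0.937 with an estimated correlation), and so were cytosolic ribosomal proteins, at 0.60 over 63 genes (camera adjusted p = 0.000623; adjusted p = 0.937 with an estimated correlation). In neither list did a member pass, over all genes or adjusted over the list alone. Ndufs7 was 0.36 ± 0.083, Ndufb5 0.48 ± 0.013, Ndufv1 0.34 ± 0.15 and Ndufc1 0.76 ± 0.053 (n = 2). Rpl39 was 1.52 ± 0.071, Rplp1 1.82 ± 0.70, Rpl41 1.78 ± 0.16 and Rps24 1.44 ± 0.042. The ribosomal medians of the 2 arrays were 0.21 and 0.91, and those of oxidative phosphorylation 0.25 and 0.60. Genes of glycolysis and hypoxia had a median of 0.45 over 33 genes (camera adjusted p = 0.0333; adjusted p = 0.937 with an estimated correlation). Ndrg1 rose by 1.16 ± 0.14 and Pfkfb4 by 0.68 ± 0.23 (n = 2), 31 members did not pass, and adjusted over the list alone 4 were higher and 1 lower. Hk1 was -1.50 ± 0.43, against the list, and Eno2 1.88 ± 0.52. Mesothelial and visceral fibroblast markers had a median of 0.94 over 18 genes (camera adjusted p = 0.00769; adjusted p = 0.937 with an estimated correlation), and none passed, over all genes or adjusted over the list alone. Wt1 was 2.13 ± 0.20, Lrrn4 2.96 ± 0.40, Nr2f1 1.0 ± 0.45 and Gpm6a 0.40 ± 0.14. Hox genes were shifted down, at -0.30 over 35 genes (camera adjusted p = 0.00412; adjusted p = 0.937 with an estimated correlation). The posterior genes Hoxd13 and Hoxa13 fell, at -1.74 ± 0.12 and -1.98 ± 0.62 (n = 2), and 33 did not pass, with Hoxd9 at -0.98 ± 0.10 and Hoxa9 at -0.83 ± 0.26. Of the 35, 0 were higher and 8 lower when adjusted over the list alone. Of all named genes 7.19% passed in the PARP-1 null, and no list here had a larger share of members past. Without the second PARP-1 null array none of the 5 lists passed camera: ribosomal 0.21 (adjusted p = 0.294), oxidative phosphorylation 0.25 (0.294), glycolysis 0.27 (0.336), Hox -0.38 (0.0698) and mesothelial 0.84 (0.0698). Without the first array the mesothelial list (0.78, camera adjusted p = 0.0669) did not pass.

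In the double mutant S100a8, a subunit of the neutrophil and monocyte protein calprotectin, rose by 4.76 ± 0.18 (mean ± SD, n = 2), with -1.17 ± 0.58 in the Wrn mutant and 1.68 ± 0.45 in the PARP-1 null. The platelet chemokine gene Ppbp rose by 4.33 ± 0.55, against -1.17 ± 0.74 and 1.47 ± 0.16 in the single mutants (n = 2). Rnase2a, an eosinophil-associated ribonuclease gene, rose by 4.41 ± 0.72 and was exactly 0 on both Wrn mutant arrays. Ifi202b (4.66 ± 0.20), Ptprv (4.46 ± 0.95), Gbp2b (3.79 ± 0.47) and Atp10d (3.70 ± 0.50) rose as in the PARP-1 null. Otud7a rose by 4.10 ± 0.86, Mgarp by 3.66 ± 0.094 and the neural crest transcription factor gene Sox10 by 3.59 ± 0.41, the last with 2.24 ± 0.084 in the PARP-1 null and 0.10 ± 0.46 in the Wrn mutant (n = 2). Among genes that fell were Nbeal2 (-5.11 ± 0.11), Serpinb9c (-4.99 ± 0.13), Vwa5b1 (-4.69 ± 0.27) and the chemokine receptor gene Ccr10 (-4.50 ± 0.043). Xlr5c (-4.25 ± 0.28), the matrix protein gene Dpt (-4.15 ± 0.13), Hes5 (-4.11 ± 0.40) and the calcium channel gene Cacna2d2 (-4.08 ± 0.13) fell too (n = 2). The meiotic MutS homologue gene Msh5 fell, at -4.07 ± 0.13, and Aspg at -3.89 ± 0.089. Adjusted p-values of these genes ran from 0.0104 to 0.0429 (limma, Benjamini-Hochberg). In all, 3052 named genes passed, 1669 higher and 1383 lower, 1598 of them at least 2-fold. The split by direction was not stable. By the 2-fold rule 777 rose and 996 fell, and more genes fell than rose without either double-mutant array. Under scale normalization between arrays 1013 passed, 596 higher and 417 lower, fewer than the 1223 of the PARP-1 null in that fit. With the array number as a block 1215 passed. The count was 32 and 185 without the first and second double-mutant array, 1308 without either Wrn mutant array, 909 without either PARP-1 null array, and 0 when fitted on the double-mutant arrays alone. With each array left out in turn, only Ifi202b of the 20 genes passed every time (adjusted p from 0.0235 to 0.0455, limma, Benjamini-Hochberg).

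Mitosis genes were shifted up in the double mutant, with a median of 0.76 over 41 genes (camera adjusted p = 3.25e-05; adjusted p = 0.993 with an estimated correlation). Ect2, a regulator of cell division, rose by 1.16 ± 0.087, the centromere histone gene Cenpa by 1.35 ± 0.0071, the cyclin gene Ccnb2 by 1.13 ± 0.16 and the spindle midzone gene Prc1 by 0.72 ± 0.061 (n = 2). Of the 41 members, 19 rose, 2 fell and 20 did not pass; adjusted over the list alone, 25 were higher and 2 lower. Genes of oxidative phosphorylation had a median of 0.64 over 56 genes (camera adjusted p = 3.25e-05; adjusted p = 0.993 with an estimated correlation). Ndufs7 (0.66 ± 0.0027), Ndufv1 (0.64 ± 0.057), Ndufb5 (0.66 ± 0.049) and Ndufs1 (0.51 ± 0.21) were among the 5 that rose (n = 2), 51 did not pass, and adjusted over the list alone 0 did. Ribosomal proteins had a median of 0.51 over 63 genes (camera adjusted p = 0.00598; adjusted p = 0.993 with an estimated correlation). Rpl39 (1.71 ± 0.65), Rplp1 (2.13 ± 0.54) and Rpl41 (1.96 ± 1.01) rose, 60 did not pass, Rps24 (1.63 ± 0.92) among them, and adjusted over the list alone 0 did. The ribosomal medians of the 2 arrays were 0.043 and 1.22. Hox genes had a median of -0.42 over 35 genes (camera adjusted p = 0.0103; adjusted p = 0.993 with an estimated correlation). Hoxa13 (-2.27 ± 0.015), Hoxd13 (-1.01 ± 0.24), Hoxd9 (-1.30 ± 0.23) and Hoxa9 (-1.27 ± 0.040) were among the 6 that fell (n = 2), 29 did not pass, and adjusted over the list alone 0 were higher and 6 lower. Interferon-response genes, shifted up in the Wrn mutant, were shifted down in the double mutant, at -0.41 over 54 genes (camera adjusted p = 0.0177; adjusted p = 0.993 with an estimated correlation). The peptide transporter gene Tap1 (-1.48 ± 0.23), Ifi205 (-3.02 ± 0.46) and Isg20 (-0.89 ± 0.23) were among the 9 that fell, while Gbp2 rose by 1.98 ± 0.21 (n = 2), against the list. The other 44 did not pass, and adjusted over the list alone 1 was higher and 9 lower. Of all named genes 18.5% passed in the double mutant. Only the mitosis list had a clearly larger share of members past, so members named from the other lists add no support. Without the second double-mutant array the ribosomal (0.043, adjusted p = 0.641), interferon (-0.29, 0.244) and oxidative phosphorylation (0.32, 0.0535) lists did not pass camera.

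**Figure D2:**
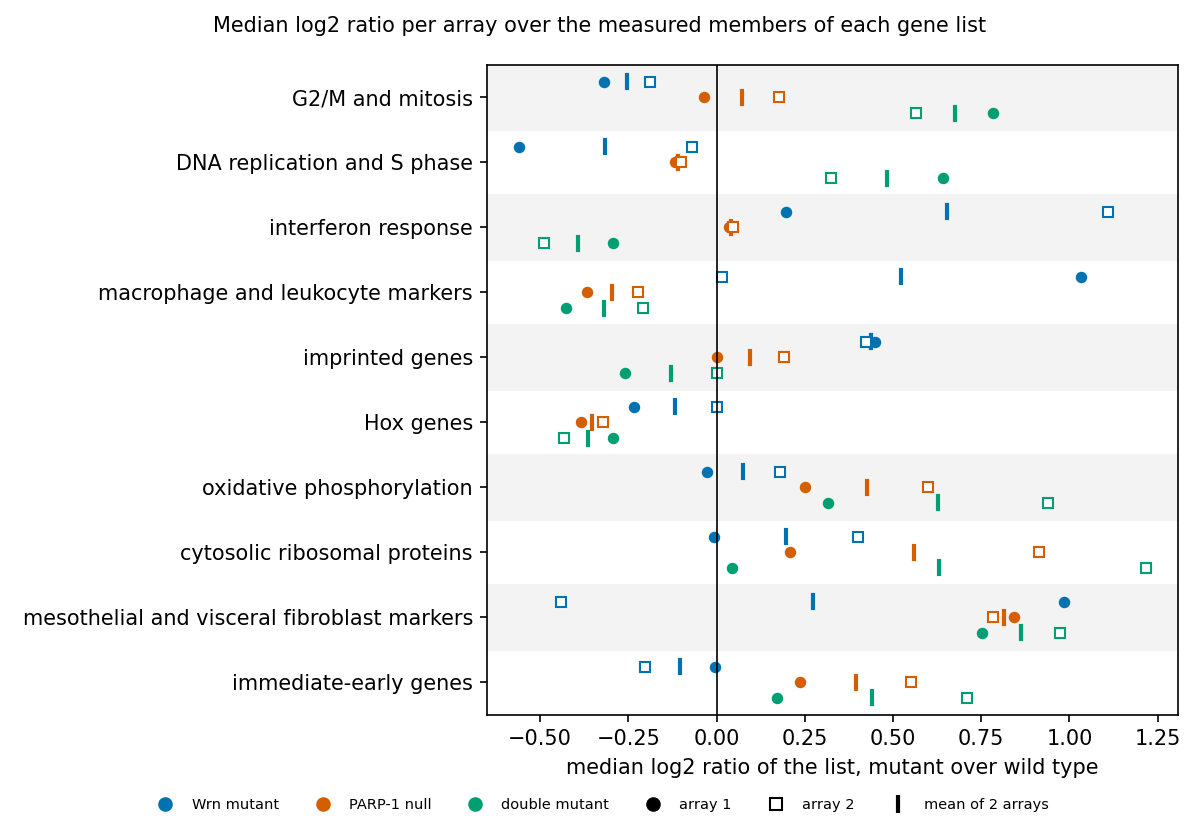
Median log2 ratio of 10 gene lists on each array, with circles for the first and squares for the second array of a genotype. Mitosis genes stood at 0.78 and 0.56 in the double mutant and at -0.32 and -0.19 in the Wrn mutant.

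Against the Wrn mutant, the double mutant had the largest gaps in Ifi202b, at 6.11 (SE 0.12), S100a8, at 5.94 (SE 0.40), and Ppbp, at 5.5 (SE 0.49) (n = 2 arrays per genotype). None of the genes named here passed, with adjusted p-values from 0.0557 to 0.233 and 0.719 for Wrn (limma, Benjamini-Hochberg). Rnase2a was 4.41 (SE 0.43), Atp10d 4.10 (SE 0.42), Otud7a 4.08 (SE 0.49) and Ptprv 4.07 (SE 0.57). Cck, which encodes the peptide cholecystokinin, was 4.01 (SE 0.62), Gbp2b 3.53 (SE 0.36) and Tepp 3.24 (SE 0.21). On the other side were Fcrls (-5.0, SE 0.35), Ctsc (-4.87, SE 0.23), Nbeal2 (-4.49, SE 0.27) and Emcn (-3.93, SE 0.87), an endothelial sialomucin gene. Ifi205 was -3.60 (SE 0.40), Arsk -3.51 (SE 0.26), Zfp874a -3.34 (SE 0.20) and Apoa2 -3.01 (SE 0.25). Klra7 was -3.01 (SE 0.23), Cldn1, a tight junction gene, -2.95 (SE 0.21), Parp1 -2.56 (SE 0.20) and Wrn -0.23 (SE 0.24). No named gene passed, and 2500 had an unadjusted p under 0.05 (limma). Without genes that were exactly 0 on any array, 38 passed, 21 higher and 17 lower. These included Ifi202b (adjusted p = 0.00189), S100a8 (0.0113), Ppbp (0.0223), Ctsc (0.0101), Nbeal2 (0.0125), Fcrls (0.0125), Nr4a1 (0.0313), Mest (0.0307) and Parp1 (0.0307) in limma with Benjamini-Hochberg. The count was 387 and 60 without the first and second Wrn mutant array, 0 without either PARP-1 null array, and 15 and 17 without the first and second double-mutant array.

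Mitosis genes were shifted up in the double mutant against the Wrn mutant, with a median of 0.93 over 41 genes (camera adjusted p = 8.72e-14; adjusted p = 0.834 with an estimated correlation). Over all genes no member passed, and adjusted over the list alone 26 were higher and 0 lower, with Ect2 at 1.10 (SE 0.065), Ccnb2 at 1.29 (SE 0.11), Cenpa at 1.22 (SE 0.13) and the mitotic kinase gene Aurka at 1.61 (SE 0.18). Replication genes were at 0.75 over 41 (camera adjusted p = 2.35e-09; adjusted p = 0.834 with an estimated correlation), with Rrm1 at 1.19 (SE 0.16), Orc1 at 1.89 (SE 0.26), Lig1 at 0.89 (SE 0.16) and Mcm5 at 1.43 (SE 0.28), 0 past over all genes or adjusted over the list alone. Oxidative phosphorylation was at 0.60 (camera adjusted p = 3.65e-06; adjusted p = 0.834 with an estimated correlation), with Ndufv1 at 0.70 (SE 0.13), Ndufs7 at 0.51 (SE 0.12), Cyc1 at 0.61 (SE 0.14) and Cox5b at 0.85 (SE 0.20), 0 past either way. Immediate-early genes, which respond to growth stimuli, were at 0.62 (camera adjusted p = 0.0016; adjusted p = 0.834 with an estimated correlation), with Nr4a1 at 2.32 (SE 0.14), Jun at 0.92 (SE 0.082), Ier2 at 0.91 (SE 0.15) and Egr2 at 1.77 (SE 0.31), 2 higher adjusted over the list alone. RecQ helicases and Wrn partners were at 0.38 (camera adjusted p = 0.00746; adjusted p = 0.834 with an estimated correlation), with Rpa1 at 1.66 (SE 0.25), Top2a at 0.88 (SE 0.18), Blm at 0.63 (SE 0.13) and Pold2 at 0.72 (SE 0.16), 0 past either way. Interferon-response genes were shifted down, at -0.98 over 54 (camera adjusted p = 1.51e-12; adjusted p = 0.834 with an estimated correlation), with 0 higher and 6 lower adjusted over the list alone. Ifi205 was -3.60, Isg20 -1.04 (SE 0.12), Tgtp1 -0.98 (SE 0.12) and Irgm1 -1.99 (SE 0.25). Macrophage markers were at -0.74 (camera adjusted p = 5.26e-05; adjusted p = 0.834 with an estimated correlation), with Cd48 at -2.30 (SE 0.37), C1qc at -1.68 (SE 0.41), C1qb at -1.65 (SE 0.43) and Mrc1 at -1.04 (SE 0.27), 0 past either way. Imprinted genes were at -0.38 (camera adjusted p = 0.000412; adjusted p = 0.834 with an estimated correlation), with Mest at -3.0 (SE 0.26), Peg3 at -2.38 (SE 0.28), Cdkn1c at -1.90 (SE 0.50) and Plagl1 at -2.80 (SE 0.77), 2 lower adjusted over the list alone. The PARP family was at -0.36 (camera adjusted p = 0.0232; adjusted p = 0.834 with an estimated correlation), with Parp1 the 1 lower member adjusted over the list alone, Parp12 at -1.44 (SE 0.44), Parp9 at -0.96 (SE 0.35) and Parp3, against the list, at 0.29 (SE 0.093). This list holds Parp1, which the double mutant lacks by design, so part of its camera result was fixed beforehand. The PARP family without Parp1 was not tested. Hox genes were at -0.42 and other matrix proteins at -0.16 (camera adjusted p = 0.0316 in each; adjusted p = 0.834 with an estimated correlation), 0 past either way. Hoxb9 was -1.22 (SE 0.30), Hoxa9 -0.85 (SE 0.23), Hoxd3 -0.88 (SE 0.29) and Hoxd13, against the list, 0.63 (SE 0.17). Aspn was -3.12 (SE 0.44), Mgp -1.77 (SE 0.30), Ogn -1.47 (SE 0.21) and Mfap5, against the list, 1.46 (SE 0.22). With each array left out in turn, 4 of the 11 lists passed camera every time. Without the first Wrn mutant array macrophage (adjusted p = 0.104) and RecQ (0.140) did not, without the second Hox (0.472), immediate-early (0.0856) and matrix (0.746), all in camera. The PARP family (0.111) was lost without either PARP-1 null array, matrix (0.117) without the first double-mutant array, and Hox (0.115), immediate-early (0.167), matrix (0.0723) and oxidative phosphorylation (0.115) without the second, all camera adjusted p.

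Against the PARP-1 null, the double mutant showed S100a8 at 3.09 (SE 0.40) and Ppbp at 2.86 (SE 0.49) (n = 2 arrays per genotype). The Y-linked gene Eif2s3y was 5.41 (SE 2.21), and it also differed between arrays of one genotype, at 0.84 and -4.48 in the Wrn mutant. Paip1 was 2.57 (SE 0.18), the leukocyte integrin gene Itgax 2.38 (SE 0.27), Sval2 2.49 (SE 0.61), Samt2b 2.26 (SE 0.31), Rprd1b 2.14 (SE 0.16), the scavenger receptor gene Marco 2.27 (SE 0.41) and Mcemp1 1.65 (SE 0.090). On the other side were H2bc18 (-3.40, SE 0.31), Mybpc1 (-2.96, SE 0.25), the carbonic anhydrase gene Car6 (-2.66, SE 0.56), Scara5 (-2.70, SE 0.54) and the interferon-inducible GTPase gene Iigp1 (-2.55, SE 0.98). Pi4k2b was -2.28 (SE 0.38), Lce1i -2.16 (SE 0.38), Rtl3 -2.15 (SE 0.43), Clba1 -1.83 (SE 0.12), Tigar -1.82 (SE 0.23), Parp1 -0.33 (SE 0.20) and Wrn 0.61 (SE 0.24). None of these passed, with adjusted p-values from 0.289 to 0.772 (limma, Benjamini-Hochberg). No named gene did, 1181 had an unadjusted p under 0.05, and without genes at exactly 0 on any array the count was 0 as well. It was 286 without the first PARP-1 null array and 14 and 15 without the first and second double-mutant array. Mitosis genes were shifted up in the double mutant, at 0.65 over 41 genes (camera adjusted p = 1.71e-11; adjusted p = 0.997 with an estimated correlation), 7 higher and 0 lower adjusted over the list alone. Ect2 was 0.76 (SE 0.065), Cenpa 1.06 (SE 0.13), Cdc20 1.27 (SE 0.17) and Prc1 0.65 (SE 0.10). Replication genes were at 0.52 (camera adjusted p = 1.25e-06; adjusted p = 0.997 with an estimated correlation), with Orc1 at 1.10 (SE 0.26), Mcm2 at 0.67 (SE 0.17), Gins2 at 0.45 (SE 0.13) and Rrm1 at 0.56 (SE 0.16), 0 past over all genes or adjusted over the list alone. RecQ helicases and partners were at 0.29 (camera adjusted p = 0.0379; adjusted p = 0.997 with an estimated correlation), with Recql4 at 0.75 (SE 0.16), Blm at 0.51 (SE 0.13), Top2a at 0.61 (SE 0.18) and Xrcc5, against the list, at -0.34 (SE 0.051), 0 past either way. Interferon-response genes were at -0.35 (camera adjusted p = 7.32e-05; adjusted p = 0.997 with an estimated correlation), with Irf7 at -1.35 (SE 0.38), Isg20 at -0.71 (SE 0.12), Tap1 at -0.66 (SE 0.17) and Ifi205 at -1.42 (SE 0.40), 0 past either way. The interferon list did not pass camera without the first PARP-1 null array (adjusted p = 0.106) or the second double-mutant array (0.114). The RecQ list did not without either Wrn mutant array (camera adjusted p = 0.0895) or the first PARP-1 null array (0.394), or without genes at exactly 0 (0.0512).

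Between the single mutants 1 gene passed: Ifi202b was higher in the PARP-1 null than in the Wrn mutant by 6.54 (SE 0.12) (n = 2 arrays per genotype; limma, Benjamini-Hochberg adjusted p = 0.0436), while 1452 genes had an unadjusted p under 0.05. The count was 342 and 317 without the first Wrn mutant and first PARP-1 null array and 0 without any other array. Without genes at exactly 0 on any array, 28 passed, 15 higher, with H2bc18 at 6.33 (SE 0.33 in that fit) and Lce1i at 4.96 (SE 0.37), and 13 lower, with Ctsc at -5.40 (SE 0.28), Fcrls at -4.85 (SE 0.35), Nbeal2 at -4.81 (SE 0.31) and Apoa2 at -3.74 (SE 0.29). Parp1 was -2.24 (SE 0.20) and Wrn -0.83 (SE 0.24), not past. Of the lists, 6 were higher and 5 lower in the PARP-1 null by camera, each with an adjusted p = 0.904 with an estimated correlation, and over all genes no member passed. Mitosis (0.32, adjusted p = 1.25e-06), oxidative phosphorylation (0.36, 2.45e-05, with all 56 genes above 0), immediate-early (0.46, 0.00135), replication (0.27, 0.00142), glycolysis (0.31, 0.0174) and ribosomal genes (0.39, 0.0174) were higher by camera. Interferon (-0.57, adjusted p = 8.25e-08), macrophage (-0.82, 1.25e-06), imprinted (-0.34, 0.00481), Hox (-0.29, 0.010) and erythroid genes (-0.15, 0.0234) were lower by camera. Adjusted over the list alone, Nr4a1 (1.95, SE 0.14) was the 1 higher immediate-early gene, Mest (-2.15, SE 0.26) and Peg3 (-1.92, SE 0.28) the 2 lower imprinted genes, and no other list had one. With each array left out in turn, only mitosis, interferon and macrophage of the 11 lists passed camera every time. Without the second PARP-1 null array the ribosomal median was 0.033 (camera adjusted p = 0.920), glycolysis 0.050 (0.309), oxidative phosphorylation 0.15 (0.0693), Hox -0.28 (0.0693) and erythroid -0.26 (0.112), and without the first Hox was -0.22 (0.0687), imprinted -0.27 (0.148) and erythroid -0.24 (0.0891). Without the first Wrn mutant array replication was 0.024 (camera adjusted p = 0.859), ribosomal 0.22 (0.708) and oxidative phosphorylation 0.28 (0.0580), and without the second glycolysis was 0.20 (0.452), Hox -0.096 (0.457), immediate-early 0.39 (0.152), imprinted -0.33 (0.0584) and erythroid -0.15 (0.143).

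No gene departed from the sum of the single mutants in the double mutant (limma, Benjamini-Hochberg), and 1963 had an unadjusted p under 0.05. Parp1 was -0.11 (SE 0.24) and Wrn -0.10 (SE 0.29) there. Any dye bias enters this contrast once with a minus sign. Without genes at exactly 0 on any array 80 passed, 49 above and 31 below the sum, and the count was 356 and 265 without the first Wrn mutant and first PARP-1 null array, and 14 and 13 without the double-mutant arrays. In the mean of all mutants 5333 named genes passed, 2766 higher and 2567 lower, which holds dye bias and any trait of the wild-type pools in full. Parp1 was -1.82 (SE 0.080) there, and Wrn, at 0.36 (SE 0.10), did not pass. The count ran from 2310 without the second PARP-1 null array to 3601 without the first Wrn mutant array.

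Most calls of the PARP-1 null were shared with the double mutant: 484 genes rose and 527 fell in both, against 55.5 and 53.5 for independent lists, and 4 went opposite ways. Ifi202b, Ptprv, Atp10d and Gbp2b rose and Nbeal2, Ctsc and Fcrls fell in both. The Wrn mutant shared 100 higher and 178 lower genes with the PARP-1 null, such as Pdgfrl, Igf2, Xlr5c and Serpinb9c, and 112 and 182 with the double mutant, with 7 and 8 in opposite directions. Of the 3052 calls in the double mutant, 264 were made in the same direction in both single mutants, 747 in the PARP-1 null only, 30 in the Wrn mutant only and 2011 in neither. This split rests on the threshold and does not make the 2011 particular to the double mutant. In the main fit no named gene passed against either single mutant. Under scale normalization the double mutant had 1013 calls against 1223 in the PARP-1 null. Across genes, group means of the PARP-1 null and double mutant correlated at 0.754. The Wrn mutant and double mutant were at 0.647, and the single mutants at 0.614. Simulated unchanged groups gave 0.503, 0.507 and 0.505, a level set by the simulation and not measured here. The simulation gave wild-type and mutant values equal spread and let same-numbered arrays share wild-type values. Measured deviations of same-numbered arrays correlated at only -0.114, -0.168 and 0.171. Single arrays correlated at 0.606, 0.590 and 0.728 within the Wrn mutant, PARP-1 null and double mutant. The first PARP-1 null array correlated above its own duplicate with both double-mutant arrays (0.739 and 0.752) and with both Wrn mutant arrays (0.601 and 0.620), and by Spearman correlation with the double-mutant arrays only (0.717 and 0.729 against 0.652). Every array had the same dye order and a wild-type partner, whose pools may be shared, so these overlaps do not separate genotype from dye or wild type. The comparisons with wild type also share an estimate of spread for each gene. Calls of one gene are therefore not independent, and the counts for independent lists are too low a yardstick.

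Genes within 20 Mb of Parp1 were called more often than others in both lines without PARP-1 when all arrays were used, and in no fit with 1 array left out did this pass (adjusted p from 0.181 to 1, exact tests, Benjamini-Hochberg). In the PARP-1 null these were 31 of 263, or 11.8% against 7.11% elsewhere (odds ratio 1.75, 95% interval 1.15 to 2.56; Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0384). In the double mutant 65 were called, or 24.7% against 18.4% (odds ratio 1.46, interval 1.08 to 1.94; exact test, Benjamini-Hochberg adjusted p = 0.0384). In the Wrn mutant 9 were, with an odds ratio of 1.48 (adjusted p = 0.439, exact test, Benjamini-Hochberg). Around Wrn the odds ratios over 180 genes were 1.44, 1.01 and 0.988 in the Wrn mutant, PARP-1 null and double mutant. Ifi202b, Ifi205, Apoa2 and Cd48 lie within 20 Mb of Parp1. Leaving out 1 array moved the odds ratio from 1.06 to 3.51 in the PARP-1 null and from 0.682, without the second double-mutant array, to 4.27 in the double mutant. Near Wrn it ran from 1.41 to 5.19 in the PARP-1 null and from 1.13 to 6.29 in the double mutant, so the loci were not set apart there. Within 10 Mb of Parp1 it was 1.69 (adjusted p = 0.278) and 1.28 (adjusted p = 0.573, exact tests, Benjamini-Hochberg). All of these exact tests take genes as independent, which neighbours may not be.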

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

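The tests that weigh explanations here were all chosen after the results were seen. Ifi202b differed between the single mutants by 6.54 and belongs to 153 genes that set the 4 arrays without PARP-1 apart from both Wrn mutant arrays by at least 1 log2 unit, 80 of them higher and 73 lower. The highest number in any other of the 15 ways to split 6 arrays into 4 and 2 was 37, and the share of splits cannot go below 0.0667. Ifi202b, Ptprv, Atp10d, Gbp2b and Otud7a were higher on these arrays, and Ctsc, Nbeal2, Fcrls, Zfp874a and Arsk lower. A segment of donor-strain chromosome around the targeted gene could explain those near it. Apoa2, Itln1, Cd48, Cd84, Cadm3, Ifi202b and Ifi205 lie within 20 Mb of Parp1, with an odds ratio of 3.05 (95% interval 1.19 to 6.53, Fisher's exact test p = 0.0108). The test takes genes as independent, which genes of 1 region, such as Ifi202b and Ifi205, may not be. Interval and p may thus overstate the evidence. Of the separated genes with a position, Parp1 itself left out, 95.4% lie outside this window, Ctsc, Nbeal2 and Fcrls on other chromosomes. A segment of that size does not hold them. The window covers 263 genes against 16198 elsewhere, so a high share elsewhere was fixed beforehand and tests nothing. Other segments that differ between the lines were not told apart from a loss of PARP-1 itself. Of the far genes, 36 had a separated neighbour within 1 Mb, against a median of 27 in 10000 shuffles (permutation p = 0.0905), and no independent line was analysed here. Cd48 is also in the macrophage and leukocyte list. Whether the cell content of the pools set such genes apart was not tested.

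Interferon-response genes were shifted down in the double mutant (-0.98) and in the PARP-1 null (-0.57) against the Wrn mutant, and macrophage markers were as well (-0.74 and -0.82). None of these 4 passed camera with an estimated correlation (adjusted p = 0.834 and 0.904), and the -0.74 did not pass camera without the first Wrn mutant array (adjusted p = 0.104). More macrophages in the Wrn mutant pools could raise both lists. On the first Wrn mutant array the macrophage median was 1.03 and exceeded the interferon median by 0.84 (permutation p = 1e-04, the smallest possible), which a larger share of macrophages may explain. On the second the macrophage median was 0.014 and the interferon median 1.11, a difference of -1.10 (permutation p = 5e-04). Macrophages are thus unlikely to be the source of the interferon genes there, such as Ifi47 and Irgm1. Both permutations shuffled gene labels within 1 array. Their p-values take genes as independent and do not measure the spread between pools. A wild-type pool low in interferon genes would give the same 1.11 and was not ruled out, since the pool on each array is not given in the sources used here.

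Mitosis genes were shifted up in the double mutant against the Wrn mutant (0.93) and the PARP-1 null (0.65), and replication genes too (0.75 and 0.52). None of these 4 passed camera with an estimated correlation (adjusted p = 0.834 and 0.997). Ect2, Cenpa and Ccnb2 were among them. Wild-type RNA on the second double-mutant array, as its strain label would have it, is unlikely, since Parp1 was -2.59 there. A single array is unlikely as well, because the lowest double-mutant median lay 0.75 above the highest Wrn mutant median. Growth state of the pooled cultures apart from genotype could give the same shift: the medians of the 2 Wrn mutant arrays differed by 0.13, but growth was not recorded in the sources used here.

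Other lists that differed between genotypes are given as values, and none passed camera with an estimated correlation (adjusted p = 0.834, 0.997 and 0.904 in the order given). In the double mutant against the Wrn mutant the medians were 0.60 for oxidative phosphorylation, 0.62 for immediate-early genes, 0.38 for RecQ helicases and Wrn partners, -0.38 for imprinted genes, -0.36 for the PARP family, -0.42 for Hox genes and -0.16 for other matrix proteins. The PARP family holds Parp1, lost by design, and was not tested without it. Against the PARP-1 null the double mutant had -0.35 for interferon-response genes and 0.29 for RecQ helicases and partners. In the PARP-1 null against the Wrn mutant the medians were 0.39 for ribosomal proteins, 0.27 for replication, 0.32 for mitosis, 0.31 for glycolysis and hypoxia, 0.46 for immediate-early genes and 0.36 for oxidative phosphorylation. The same comparison gave -0.29 for Hox genes, -0.34 for imprinted genes and -0.15 for erythroid markers. Of its lists here only mitosis passed camera with each array left out in turn, and without 1 array the median was 0.033 for ribosomal proteins, 0.024 for replication and 0.050 for glycolysis and hypoxia. Among the 4159 spots without a symbol, 456 had a mean log10 ratio under -1 over all arrays, against 10 named genes, and what these spots measure is not given in the sources used here.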

How the results depend on the processing

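Centring on the mean, named genes alone, leaving out features at exactly 0 on all arrays, lists without genes at exactly 0, correlations with unnamed spots and the genes separating the arrays without PARP-1 were chosen after seeing the data. Reversed were Wrn in the PARP-1 null, -0.12 at first and 0.045 without its second array, and the odds ratio of genes near Parp1 in the double mutant, 1.46 at first and 0.682 without its second array. Odds ratios that never passed crossed 1 too: in the Wrn mutant near Parp1 1.48 became 0.981 without its first array and near Wrn 1.44 became 0.573 without its second, and near Wrn 1.01 became 0.817 within 10 Mb in the PARP-1 null, and 0.988 became 1.12 within 10 Mb and 1.13 to 6.29 with 1 array left out in the double mutant. No other named gene and no list turned its direction. Of 261 gene values, 238 kept their side of the threshold under scaling (18 weaker, 5 stronger), 246 with robust empirical Bayes (14 weaker, 1 stronger), 235 centred on the mean (3, 23), 246 with named genes alone (14, 1) and 243 without features at 0 on all arrays (1, 17). Without genes at exactly 0 on any array 207 of 251 did (1 weaker, 43 stronger), and with 1 array left out 1209 of 1566 (337 weaker, 20 stronger). Of 41 list results 41 stayed past camera centred on the mean and 40 without genes at exactly 0, and with 1 array left out 201 of 246. Centring on the median changed nothing, since medians were 0, and single spots moved no result past the limits. Spearman correlation did not move the mean correlations past them, but by it the first PARP-1 null array no longer correlated with the Wrn mutant arrays (0.586 and 0.644) above its duplicate (0.652).

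The Wrn mutant's 388 genes became 940 under scaling (450 higher, 490 lower), 1086 without exact 0, 730 centred on the mean, 128 with named genes alone, 614 without features at 0 on all arrays, 0 on its own arrays and 671 by the 2-fold rule. The PARP-1 null's 1187 became 2121 without exact 0, 770 with robust empirical Bayes and 0 on its own arrays. The double mutant's 3052 became 1013 under scaling (596 higher, 417 lower), 0 on its own arrays and 1773 by the 2-fold rule. Its 0 against the Wrn mutant became 3 under scaling, 38 without exact 0, 2 with robust empirical Bayes, 1238 by the 2-fold rule, and 1 each centred on the mean, with named genes alone and without features at 0 on all arrays. Against the PARP-1 null 0 became 527 by the 2-fold rule. Between the single mutants 1 became 7 under scaling, 28 without exact 0, 2 with robust empirical Bayes, 2 centred on the mean, 3 without features at 0 on all arrays, 0 on their own arrays and 819 by the 2-fold rule. Departures from the sum, 0 at first, became 80 without exact 0, 35 centred on the mean and 36 without features at 0 on all arrays. The 5333 genes of all mutants became 325 by the 2-fold rule. A fit on a comparison's own arrays has fewer residual degrees of freedom by construction; other causes were not tested. Lists past the test went from 5 to 8 centred on the mean and 9 without exact 0 in the Wrn mutant, and from 5 to 9 and 8 in the double mutant. With an estimated correlation 0 lists passed in every comparison (smallest adjusted p = 0.834, camera). By fry 0 passed in the others and 1 in the double mutant, other patterning transcription factors (fry adjusted p = 0.00763). Within 10 Mb the odds ratios near Parp1 were weaker, 1.69 and 1.28, and mean correlations with unnamed spots were 0.780 within and 0.742 between groups, against 0.641 and 0.563.

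With the array number as a block, 0 genes passed in the Wrn mutant, 0 in the PARP-1 null, 1215 in the double mutant and 0 between the single mutants. Deviations of same-numbered arrays correlated at -0.114, -0.168 and 0.171, so over all genes the numbers showed no common pairing. An effect of the number on some genes was not ruled out. Ribosomal medians, for example, were higher on the second array in both the PARP-1 null and the double mutant. Of the 261 gene values 203 kept their side of the threshold with the block and 58 no longer passed. Of the 41 list results 40 stayed past camera, and RecQ helicases and Wrn partners in the double mutant against the PARP-1 null did not (camera adjusted p = 0.0553). Leaving out 1 array gave 0 to 768 genes in the Wrn mutant, 56 to 597 in the PARP-1 null, 32 to 1308 in the double mutant, 0 to 387 and 0 to 286 for the double mutant against the Wrn mutant and PARP-1 null, 0 to 342 between the single mutants, 0 to 356 off the sum and 2310 to 3601 in all mutants. Such a fit has 2 residual degrees of freedom in place of 3, and takes a lone array to vary like the other groups; counts rose in some of these fits and fell in others, and the cause was not tested. Parp1 ran from -2.61 to -2.30 in the PARP-1 null, -2.97 to -2.59 in the double mutant and -0.31 to -0.12 in the Wrn mutant, and Wrn from -0.29 to 0.045, 0.25 to 0.71 and 0.58 to 0.84. Lists past camera ran from 3 to 10 in the Wrn mutant, 0 to 6 in the PARP-1 null, 3 to 8 in the double mutant, 7 to 15 and 2 to 7 for the double mutant against the Wrn mutant and PARP-1 null, and 6 to 12 between the single mutants. Odds ratios near Parp1 ran from 1.06 to 3.51 in the PARP-1 null, 0.682 to 4.27 in the double mutant and 0.981 to 1.20 in the Wrn mutant, and near Wrn from 1.41 to 5.19, 1.13 to 6.29 and 0.573 to 1.21. No odds ratio was formed in 8 alternatives with fewer than 20 calls. Not run were the 2-fold rule for the sum, which has no array of its own, own arrays for the sum and all mutants, which use all 6, and keeping missing values, of which there were none. Signal over background was not used here, so weak spots could not be set apart.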

Other observations

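Single members of repair and stress lists passed against wild type although their lists did not pass camera there. These genes were chosen after their values were seen. Of all named genes 2.35%, 7.19% and 18.5% passed in the Wrn mutant, PARP-1 null and double mutant. Single members past the threshold are thus no sign of a repair or stress response. A gene named for 1 genotype passed there, and values as large in another could miss the threshold. Cebpd was 1.56 in the PARP-1 null, Gar1 -1.03 and Gstt1 0.70 in the Wrn mutant. In the Wrn mutant, PARP-1 null and double mutant Ccl20 was 1.80, 1.56 and 1.92 and Cdkn2a -1.81, -1.49 and -2.20. Others differed more, such as Bok at -0.29, 0.75 and 1.67. Values alike in all 3 genotypes, such as those of Aen, Casp9, Cflar and Tnfaip3 below, may come from dye bias or the wild-type pools. Genotype is not told apart from these there. Among p53 targets, Mdm2, the negative regulator of p53, fell in the double mutant, at -1.92 ± 0.60 (mean log2 ratio ± SD, n = 2), and Gadd45a at -0.89 ± 0.44. The apoptosis genes Bbc3 and Pmaip1 fell in the PARP-1 null, at -1.24 ± 0.28 and -1.28 ± 0.047, and in the double mutant, at -1.83 ± 0.033 and -1.10 ± 0.12 (n = 2). Ccnd1, a cyclin gene, fell in both as well, at -1.22 ± 0.31 and -1.47 ± 0.31, and the nuclease gene Aen in all 3 genotypes, at -1.65 ± 0.23, -1.61 ± 0.21 and -1.60 ± 0.33. Fas, a death receptor gene, rose in the double mutant by 1.19 ± 0.11. The p53 list had 0 higher and 2 lower of 32 in the Wrn mutant, 0 and 5 in the PARP-1 null and 1 and 7 in the double mutant (camera adjusted p = 0.569, 0.245 and 0.115; adjusted p = 0.931, 0.937 and 0.993 with an estimated correlation). Adjusted over the list alone these were 0 and 3, 2 and 5, and 2 and 12. Casp9 fell in all 3, at -1.84 ± 0.39, -2.21 ± 0.050 and -2.26 ± 0.19, as did Cflar (-0.51 ± 0.074, -0.58 ± 0.045, -0.47 ± 0.087) and Tnfaip3 (-0.90 ± 0.20, -1.07 ± 0.15, -0.94 ± 0.12), while Bok (1.67 ± 0.26), Endog (0.87 ± 0.090) and Diablo (0.56 ± 0.094) rose in the double mutant (n = 2). With each array left out in turn, none of the 11 such genes in the Wrn mutant, none of 37 in the PARP-1 null and 1 of 77 in the double mutant passed every time.

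Of the double-strand break repair genes, H2ax rose in the PARP-1 null by 0.77 ± 0.13 and in the double mutant by 1.39 ± 0.051 (n = 2). The kinase gene Atm fell in both, at -0.81 ± 0.043 and -0.63 ± 0.021, and Xrcc5, which encodes Ku80, in all 3, at -0.41 ± 0.038, -0.30 ± 0.048 and -0.64 ± 0.029. In the double mutant Chek2 fell (-1.37 ± 0.33) and Rad52 (1.14 ± 0.31), Rad54b (1.22 ± 0.29) and Nbn (0.42 ± 0.081) rose (n = 2). Of strand-break repair genes, Parp2 fell there, at -1.07 ± 0.47, and Aptx rose by 0.71 ± 0.26. Of Wrn partners, the helicase genes Blm and Recql rose there by 0.58 ± 0.19 and 0.50 ± 0.13, Top1 by 0.55 ± 0.052 and Rpa1 by 0.92 ± 0.47. Telomere genes Pot1a (0.71 ± 0.32) and Nop10 (1.22 ± 0.44) rose and Gar1 (-0.97 ± 0.035) fell in the double mutant (n = 2). Of senescence regulators, Cdkn2a fell, at -2.20 ± 0.28, as did Cdkn2b (-1.24 ± 0.42) and the repressor gene Bmi1 (-1.60 ± 0.15), while Id1 (1.78 ± 0.71) and Cdkn2d (0.91 ± 0.016) rose there. Rb1 rose in all 3 genotypes, by 0.64 ± 0.083, 0.86 ± 0.033 and 1.33 ± 0.066, and Ing1 fell, at -0.57 ± 0.027, -0.45 ± 0.026 and -0.62 ± 0.14. Of antioxidant genes, Gpx2 fell in all 3, at -1.43 ± 0.10, -2.21 ± 0.24 and -0.76 ± 0.033, and the catalase gene Cat (-1.34 ± 0.50), Sod3 (-1.50 ± 0.15) and the oxidase gene Nox4 (-1.56 ± 0.40) fell in the double mutant. Others rose: Gstt2 (1.53 ± 0.036) and Nqo2 (0.50 ± 0.025) in the double mutant, Gstt1 (0.62 ± 0.11) in the PARP-1 null, and Hmox2 in both, by 0.27 ± 0.0093 and 0.55 ± 0.063 (n = 2).

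Il6, a cytokine gene, rose in the PARP-1 null by 2.77 ± 0.16 and in the double mutant by 2.89 ± 0.082 (n = 2). Csf3 rose in all 3 genotypes, by 1.29 ± 0.028, 1.29 ± 0.054 and 2.04 ± 0.28. The chemokine genes Cxcl1 (2.26 ± 0.68), Cxcl2 (2.22 ± 0.052) and Ccl20 (1.92 ± 0.46) rose in the double mutant, as did Nos2 (1.87 ± 0.29). Timp2 fell there, at -2.30 ± 0.47, with Igfbp3 (-1.33 ± 0.31) and the NF-kB subunit gene Relb (-0.54 ± 0.12), and Plau fell in the PARP-1 null, at -1.36 ± 0.27. The growth-response genes Egr1 (1.71 ± 0.56, 1.77 ± 0.26), Egr2 (1.71 ± 0.54, 2.25 ± 0.18), Nr4a1 (1.73 ± 0.067, 2.09 ± 0.17) and Junb (1.14 ± 0.30, 1.53 ± 0.020) rose in the PARP-1 null and the double mutant, and Nr4a2 fell (-1.0 ± 0.18, -0.58 ± 0.17) (n = 2). Immediate-early genes had 6 higher and 1 lower of 34 in the PARP-1 null and 8 and 1 in the double mutant (camera adjusted p = 0.119 and 0.0785; adjusted p = 0.937 and 0.993 with an estimated correlation). Adjusted over the list alone these were 10 and 2, and 8 and 1. The fat-cell regulator Pparg fell in the PARP-1 null, at -1.41 ± 0.028, and the double mutant, at -1.47 ± 0.17, as did Cebpa (-0.80 ± 0.27, -0.97 ± 0.14) and Retn (-1.70 ± 0.32, -2.02 ± 0.17). Klf15 fell in all 3, at -1.80 ± 0.16, -2.01 ± 0.0028 and -2.49 ± 0.28, and Fabp5 rose in the PARP-1 null and double mutant, by 2.00 ± 0.44 and 2.48 ± 0.49, and Cebpd in the double mutant by 1.55 ± 0.42 (n = 2). The neural genes Gap43 (1.09 ± 0.23, 1.13 ± 0.10) and Slc1a3 (2.99 ± 0.42, 2.29 ± 0.53) rose in both, and Foxd3 by 1.80 ± 0.35 in the double mutant.

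Genes of the sex chromosomes differed between arrays of one genotype. The Y-linked Eif2s3y was 0.84 and -4.48 in the Wrn mutant, -5.33 and -3.37 in the PARP-1 null and 0.12 and 2.00 in the double mutant. Uty was 0.59 and -5.66, 0 and -1.48, and -1.90 and 0.11, and Kdm5d 1.22 and -2.60, -0.69 and -2.12, and -1.49 and 1.33. Eif2s3y, Uty and Kdm5d all lay above 0 on the first Wrn mutant array and far below 0 on the second. This argues against the same RNA pools in both channels of these arrays. Xist was 0.65 and 1.01, 1.48 and 0.35, and 2.46 and 0.057. In the mean of all mutants, 99 of 849 olfactory and vomeronasal receptor genes passed, or 11.7%, against 33.4% of the 15655 others (odds ratio 0.263).

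Of the 42 lists, 27 passed camera in no comparison. Their smallest adjusted p in camera was 0.0508 for antigen presentation, 0.0931 for collagens, 0.115 for NF-kB targets and for p53 targets, 0.129 for double-strand break repair, and 0.162 for epithelial markers and for heat shock. It was 0.218 for neural markers, 0.237 for base excision repair, 0.250 for histones, 0.252 for secreted senescence factors and for smooth muscle, 0.268 for the insulin-like growth factor axis and 0.269 for adipocyte genes (camera). It was 0.310 for skeletal muscle, 0.353 for other patterning factors, 0.430 for cartilage and bone, 0.458 for oxidative stress and 0.529 for telomere maintenance (camera). The remaining lists were apoptosis, senescence regulators, endothelial markers, Wnt and cholesterol synthesis at 0.544, sex-chromosome markers at 0.628, proteases at 0.634 and TGF-beta at 0.782 (camera adjusted p).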
